A study of Mus musculus with 2 samples.

How the data were processed

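Brown adipose tissue of mice of 4 weeks was profiled as single nuclei with the 10x Genomics 3' v3 chemistry, with 8000 nuclei targeted per library and paired-end NovaSeq sequencing, per the labels' protocols. There was 1 library of genotype Flox and 1 of genotype KO. The deposited values were UMI counts per gene and barcode, made with Cell Ranger 5.0.0 per the file headers and on genome build mm10 per the submitters' processing notes. The annotation, the handling of intron reads and the settings for calling nuclei are not given in the sources used here. Each file held 22620 genes, and every barcode had at least 500 UMIs. Gene positions came from GENCODE vM21, which is on the mm10 assembly, by gene ID, and 22565 IDs had a position. Of the IDs, 42 had a symbol that more than 1 ID shared, so genes were handled by ID.

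Barcodes with fewer than 200 detected genes or more than 10% mitochondrial UMIs were removed (99 in Flox and 129 in KO). Doublets were scored with Scrublet in scanpy 1.11.5, and the highest scores were removed up to an expected rate of 0.8% per 1000 barcodes (2084 and 1341 barcodes). Counts of both libraries were scaled to 10000 per nucleus and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9) gave 17 clusters of at least 20 nuclei, without batch correction. Clusters were named from 16 marker lists fixed before the data were examined, and names carry "-like" because they rest on RNA alone. The 8 named classes had their shares compared, and the 6 classes with at least 100 nuclei in each library were compared within class. Marker genes of clusters were not read as differences between libraries.

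UMIs were summed per class and library and divided by the class total (CPM). Log2 ratios were computed with 0.5 UMI added, for genes with at least 50 UMIs in the class over both libraries. With 1 library per genotype no test between genotypes was run. Exact Poisson intervals were computed for CPM, exact binomial intervals for ratios and Clopper-Pearson intervals for shares, all at 95% and for counting error only. Genes were counted at 2-fold or more. The 29 gene lists, fixed before the data were examined, were summarised by the median log2 ratio, by members at least 1.5-fold apart, by an interval from 1000 redraws of the counts, and by the percentile among 10000 random lists matched on expression. Genes were named by a rule fixed in advance: among genes with at least 100 UMIs over both libraries and, in the library with more, at least 20 CPM and a CPM not below that of all other nuclei, the 12 at least 1.5-fold and furthest apart each way in adipocyte-like nuclei and 6 each way in other classes. Mitochondrial genes, ribosomal protein genes with symbols in Rpl or Rps, haemoglobin, sex-linked and unnamed clone genes were left out, and 2 members each way were named per list. Nfe2l1 and Ucp1 were fixed by name. The chromosome 16 segment, Zfp949 and the number of nuclei holding a named gene's UMIs were examined after the values were seen. Shares of nuclei with a Ucp1 UMI were taken after thinning each nucleus to 1000 UMIs.

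The counting was tested on simulated data for adipocyte-like nuclei, over 12310 genes: 96 of 97 genes simulated beyond 2-fold were counted, and of 12114 unchanged genes 6 were counted as higher and 2 as lower. The intervals held the simulated ratio for 95.1% of genes. Of 200 unchanged lists of 20 genes, 7.0% fell outside percentiles 2.5 to 97.5. The simulation held no spread between nuclei or mice. Alternatives fixed in advance were filters at 500 genes and 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.3 and 1.0, each library clustered alone, classes from marker scores per nucleus, TMM factors (edgeR 4.0.16), the mean CPM over nuclei, totals without mitochondrial and the 20 most abundant genes, thinning, a minimum of 20 UMIs, and a filter against free RNA. Fixed symbols that the files did not hold, such as Xist, Aldoa and Ddit3, were left out. A few genes that the naming rule picked are not reported here. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, with figures in matplotlib 3.10.9.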

Results

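Single nuclei of brown adipose tissue from mice of 4 weeks were profiled in 2 droplet RNA libraries, 1 labelled Flox and 1 labelled KO. The series design gives the KO as a knockout of Nfe2l1, the gene of the transcription factor NFE2L1 (also called NRF1), which is known to drive the genes of the proteasome. The comparison asks how brown adipocytes and the other cells of the tissue differ between the 2 genotypes. The Flox library held 16145 barcodes with 46528077 UMIs and the KO library 13030 barcodes with 43080725 UMIs. Median depth was 2375 UMIs per barcode in Flox and 2755 in KO. After filtering, 13962 and 11560 nuclei were kept, with medians of 2255 and 2644 UMIs. With 1 library per genotype no difference has a replicate check, so values are given side by side, and sizes follow fixed rules rather than a test. Intervals are 95% intervals that cover counting error only and not the spread between nuclei or mice. Expression is given as CPM, the UMIs of a gene scaled to all UMIs of the class, and log2 ratios are KO over Flox.

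Nfe2l1 itself went against the label: its transcript was more abundant in the library labelled KO. Adipocyte-like nuclei had 3694 Nfe2l1 UMIs (131 CPM, 127 to 136) in the library labelled Flox and 9135 (312 CPM, 306 to 319) in the library labelled KO, a ratio of 2.37 (2.28 to 2.47). The gene was higher in each of the 4 adipocyte-like clusters, with ratios of 2.69 in cluster 1, 2.40 in cluster 2, 1.99 in cluster 3 and 3.85 in cluster 8. Fibroblast/progenitor-like nuclei had a ratio of 1.11 (0.915 to 1.34), endothelial-like nuclei 1.14 (0.949 to 1.36), pericyte/smooth muscle-like nuclei 0.916 (80.8 and 73.6 CPM) and skeletal muscle-like nuclei 0.977 (0.558 to 1.57), so no difference was detectable there at this depth. Macrophage/monocyte-like nuclei had a ratio of 1.37 (0.949 to 2.01). T/NK-like nuclei, with 15 and 40 UMIs, had a ratio of 2.79 (1.54 to 5.54), Schwann-like nuclei, with 5 and 11 UMIs, 3.03 (1.02 to 11.7), and nuclei in no named class, with 54 and 63 UMIs, 1.74 (1.19 to 2.56). Nfe2l1 lies on chromosome 11 from 96817414 to 96829968 (mm10, minus strand), and its nearest measured neighbours Cbx1 and Copz2 had log2 ratios of -0.01 and -0.12. The deleted part of the gene is not given in the sources used here, and 3' counts outside a deleted part do not check a label. Because the gene went against the label, the libraries are called by their labels throughout, and every direction rests on those labels.

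**Figure D1:**
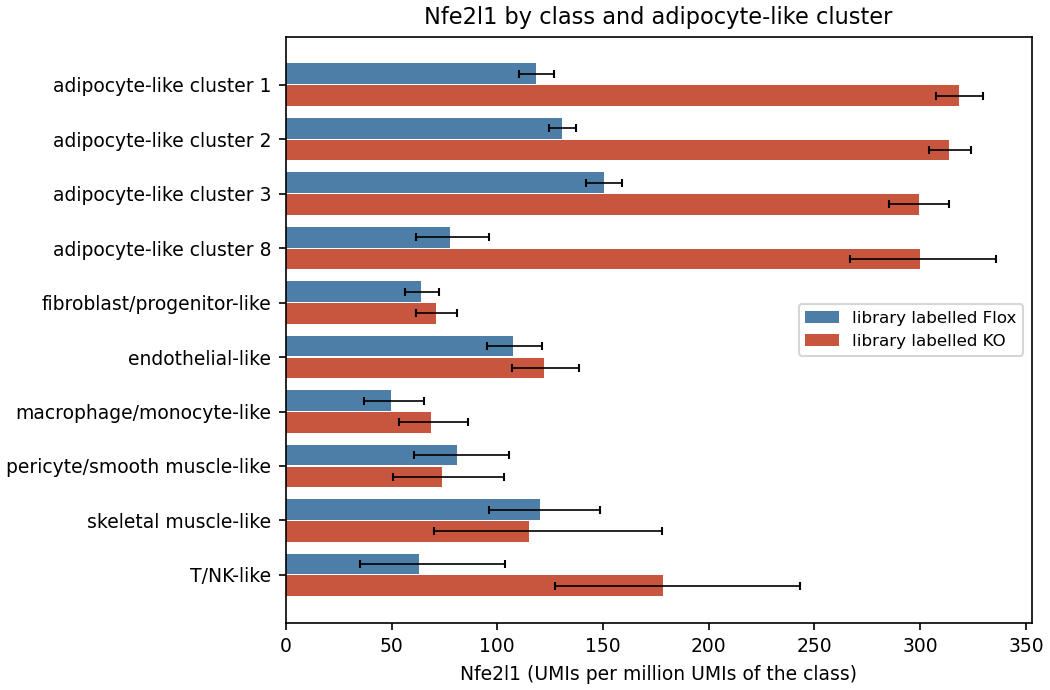
Nfe2l1 in CPM, per adipocyte-like cluster and class, in the library labelled Flox (blue) and the library labelled KO (red); error bars are exact Poisson 95% intervals. The adipocyte-like clusters lie between 77.5 and 150 CPM in Flox and between 299 and 318 CPM in KO.

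Adipocyte-like nuclei made up 63.6% (62.8 to 64.4) of the nuclei labelled Flox and 71.2% (70.4 to 72.1) of those labelled KO. By the ratio of shares, skeletal muscle-like nuclei were the class furthest apart, at 2.12% (1.89 to 2.37) in Flox and 0.623% (0.488 to 0.784) in KO, which is 296 and 72 nuclei. Lower shares in KO were also found for fibroblast/progenitor-like nuclei (14.9% and 12.4%), endothelial-like nuclei (10.3% and 7.98%) and pericyte/smooth muscle-like nuclei (2.51% and 1.91%). Macrophage/monocyte-like nuclei (3.63% and 3.19%, ratio 0.767 to 1.01) and Schwann-like nuclei (0.501% and 0.389%, ratio 0.522 to 1.15) were not told apart, while T/NK-like nuclei (0.738% and 1.03%) had a ratio of 1.40 (1.06 to 1.83). Nuclei in no named class numbered 238 in Flox and 145 in KO. How much neighbouring muscle was left on each sample is not given in the sources used here.

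**Figure D2:**
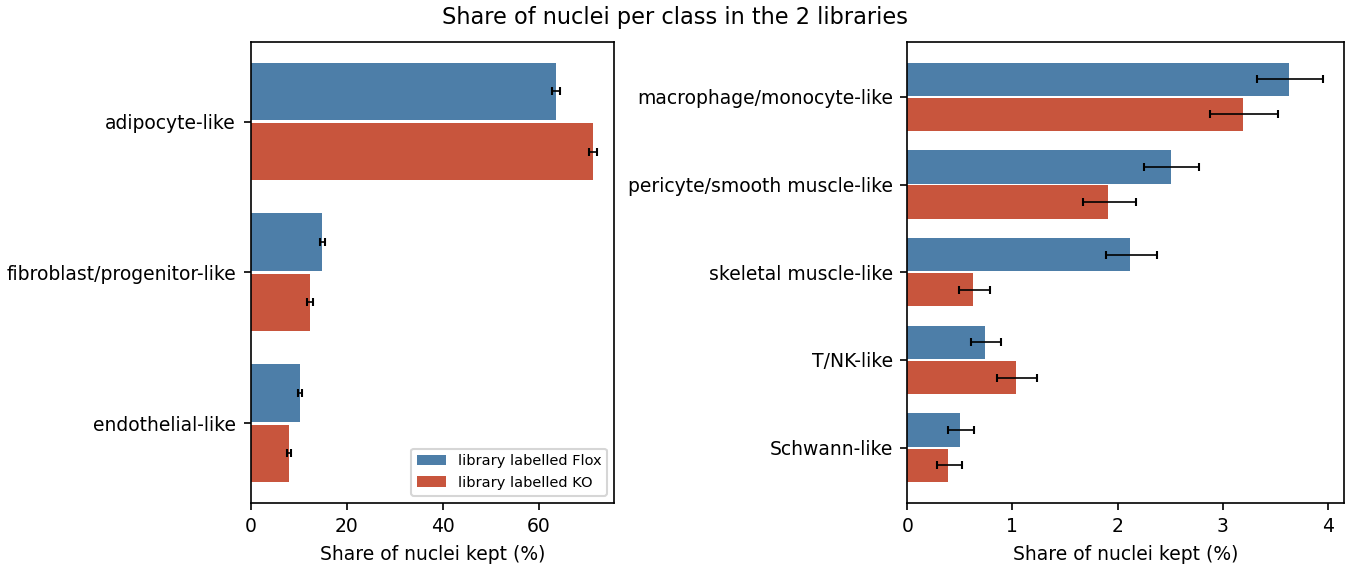
Share of kept nuclei per class (%) in the library labelled Flox (blue) and the library labelled KO (red), with Clopper-Pearson 95% intervals. Skeletal muscle-like nuclei stand at 2.12% in Flox and 0.623% in KO.

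Within adipocyte-like nuclei, proteasome genes were lower in the library labelled KO, while genes of fat oxidation, lipolysis and the respiratory chain were slightly higher. The 20S and 19S proteasome list had a median log2 ratio of -0.46 (-0.48 to -0.36), below all 10000 random lists matched on expression. Of its 34 measured genes, 12 were at least 1.5-fold lower and 0 at least 1.5-fold higher. Psmd1, a scaffold subunit of the 19S particle, stood at 152 CPM in Flox and 69.9 in KO (log2 ratio -1.12), and Psmd14, its deubiquitinase, at 130 and 70.0 (-0.89). Psmb6 and Psmb4 of the 20S core went the other way, each with a log2 ratio of 0.32. Among the partners of the proteasome, Nploc4 (-0.74) and Vcp (-0.65), which extract ubiquitinated proteins, were lower, while the list of ubiquitin and autophagy adaptors had a median of -0.06. Immunoproteasome and antigen presentation genes had a median of 0.02.

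Fatty acid oxidation genes had a median log2 ratio of 0.28 in adipocyte-like nuclei (percentile 100 among the random lists), with 16 of 18 above 0. Slc25a20, the mitochondrial carnitine carrier, had a log2 ratio of 0.60 and Acsl1, an acyl-CoA synthetase, 0.58, whereas Cpt1a stood at -0.72. The respiratory chain list had a median of 0.22 (percentile 100), with 29 of 30 genes above 0, led by the cytochrome oxidase subunits Cox8b (0.83) and Cox7a1 (0.80). Lipolysis genes had a median of 0.25 (percentile 99.99): G0s2, an inhibitor of the lipase ATGL, stood at 282 CPM in Flox and 658 in KO. The thermogenic list had a median of 0.18 (percentile 99.96), with 2 of 24 genes at least 1.5-fold higher and 0 at least 1.5-fold lower. The 2 genes are again Cox8b and Cox7a1, which are in both lists. The thermogenic median was 0.068 without cluster 3, left out as an alternative chosen after seeing the data. Adipocyte markers as a whole had a median of 0.15 (percentile 99.98), with 31 of 41 above 0. These 5 medians lie below the 1.5-fold size used for single genes. UMIs of mitochondrial genes were 0.471% of the class total in Flox and 1.28% in KO. This was not particular to adipocyte-like nuclei: over all kept nuclei the median percentages were 0.42 and 1.11. Mitochondrial genes at least 2-fold higher numbered 13 in fibroblast/progenitor-like, 10 in T/NK-like and 9 in macrophage/monocyte-like nuclei. Endothelial-like nuclei had 1 and pericyte/smooth muscle-like nuclei 0.

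**Figure D3:**
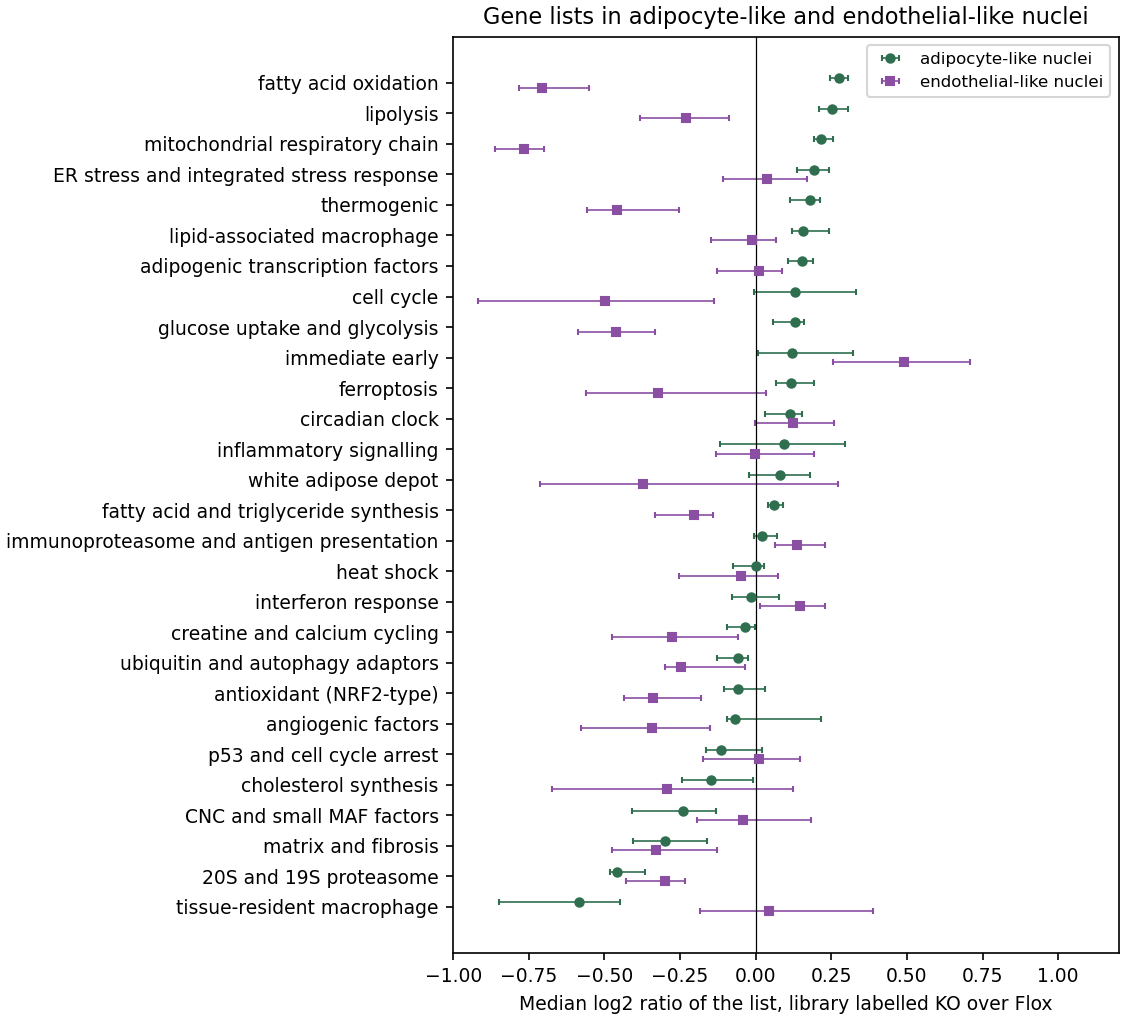
Median log2 ratio (KO over Flox) of 28 gene lists in adipocyte-like (circles) and endothelial-like nuclei (squares), with 95% counting intervals. In adipocyte-like nuclei the proteasome list lies at -0.46 and fatty acid oxidation at 0.28, whereas in endothelial-like nuclei fatty acid oxidation lies at -0.71.

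Kng1, which encodes a kininogen, was the gene furthest apart in adipocyte-like nuclei, with 4 UMIs in the library labelled Flox and 2299 (78.6 CPM) in the library labelled KO. It sits beside Adipoq, the adiponectin gene, on chromosome 16, and other genes of that segment were also higher: Kng2 had a log2 ratio of 0.90, Eif4a2 0.85, Rfc4 0.56 and Adipoq 0.24. St6gal1 on the far side of Adipoq had -0.08. Before Kng2 lay Fetub at 0.20 (25 and 30 UMIs), Dnajb11 at 0.29 (0.14 to 0.44) and then Tbccd1 at -0.11, so where the higher genes end is not sharp. Eif4a2, a translation factor used by most cells, was higher in all 6 compared classes, with log2 ratios from 0.47 to 0.85. Kng1 and Kng2 are close paralogs, so the split of reads between them is uncertain. A fixed split would keep their ratio, but there were 0.00158 Kng1 UMIs per Kng2 UMI in Flox and 0.467 in KO.

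**Figure D4:**
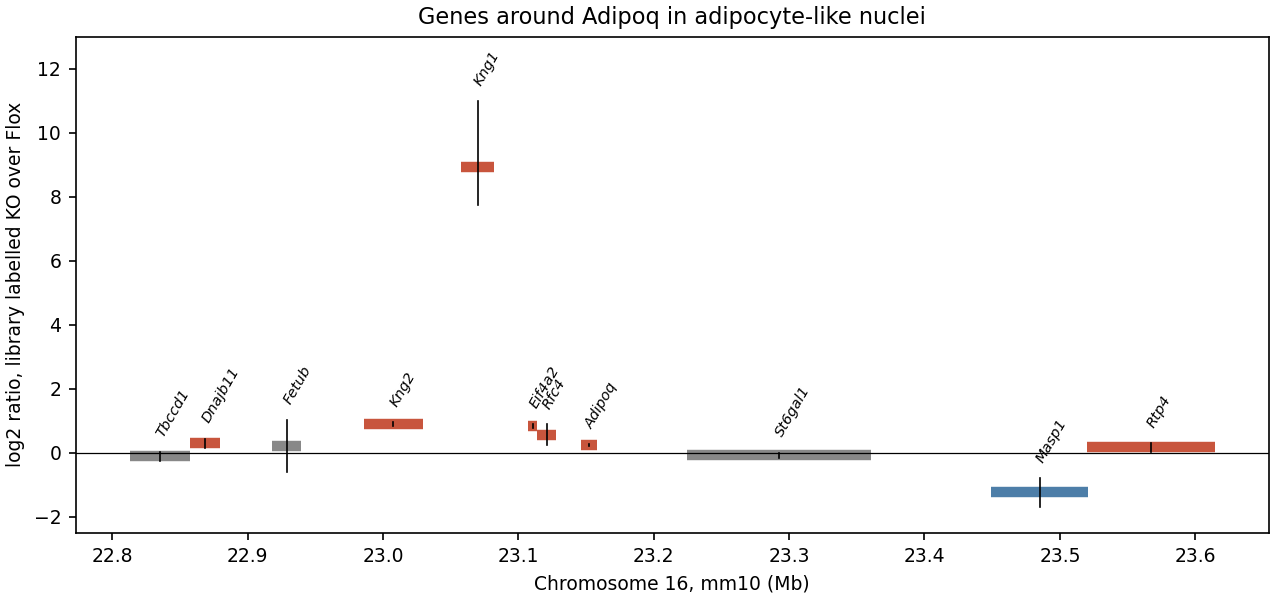
Genes with at least 50 UMIs over both libraries around Adipoq on chromosome 16 (mm10, Mb) in adipocyte-like nuclei. Boxes span the gene, their height gives the log2 ratio (KO over Flox), and vertical lines give 95% counting intervals. Kng1 lies at 8.94, Kng2 at 0.90 and Eif4a2 at 0.85.

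The other genes furthest apart in adipocyte-like nuclei included 2 adipogenic transcription factors. Cebpb stood at 57.0 CPM in Flox and 138 in KO and Cebpa at 58.1 and 114, against 6823 and 5517 for Pparg (log2 ratio -0.31); the list of adipogenic factors had a median of 0.15. Ehhadh, a peroxisomal beta-oxidation enzyme, stood at 89.4 CPM in Flox and 205.5 in KO, Acot2, a mitochondrial thioesterase, at 20.3 and 41.4, and Trarg1, a regulator of GLUT4 traffic, at 88.4 and 179. Ifi27l2a (log2 ratio 1.36), Tmem132b (0.95), Ccn1 (10.5 and 25.1 CPM) and Pmepa1 (1.08, a leading gene of cluster 1) were also higher. In the other direction, Rbfox1, a splicing factor, stood at 317 CPM in Flox and 85.3 in KO (-1.89). Aspscr1 (-1.01), which tethers GLUT4, the potassium channel gene Kcnk2 (-1.41), the necroptosis effector Mlkl (-1.29), Grip1 (-1.48), Trim43c (-1.28), Sgk2 (-1.09), Inha (-1.04) and Sh3bgrl2 (-0.98) were lower. Me1 (-1.43) and Gbp11 (-1.23) were lower too. Gbp11 leads cluster 3, and without cluster 3 its log2 ratio was 0.73. Me1 leads cluster 8, which held similar shares of adipocyte-like nuclei, 4.01% in Flox and 3.18% in KO, and it was not recomputed without that cluster.

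**Figure D5:**
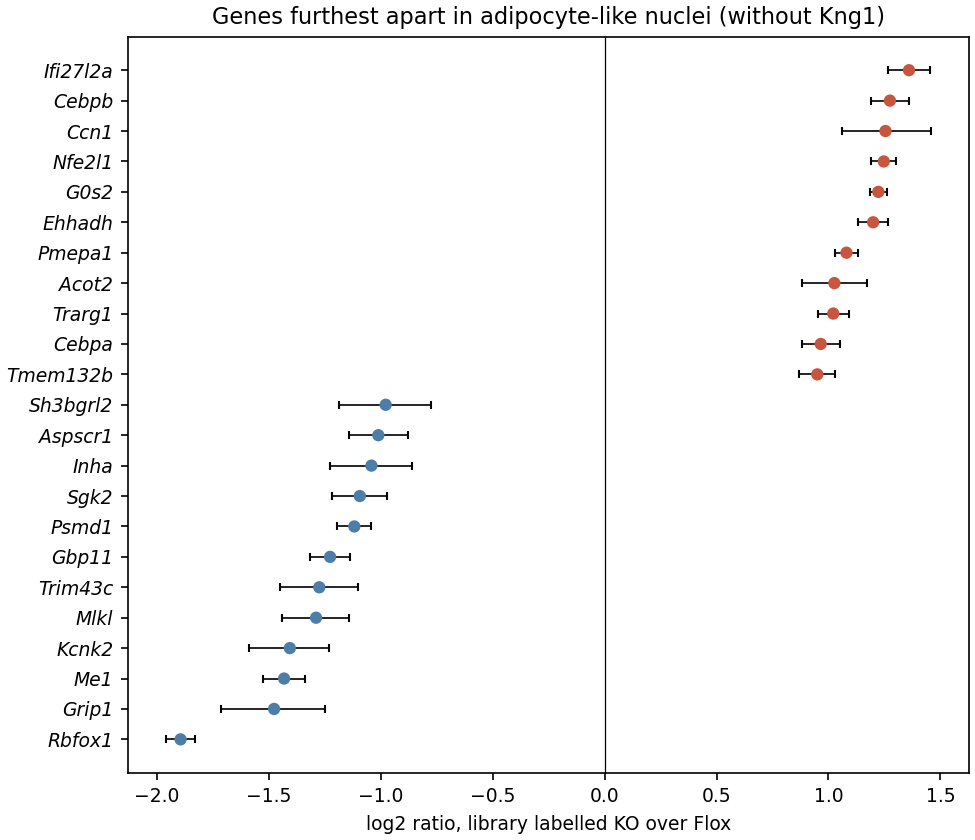
Log2 ratio (KO over Flox) of the 23 genes furthest apart in adipocyte-like nuclei by the fixed rule, Kng1 left out, with exact 95% counting intervals; red points are higher and blue points lower in the library labelled KO. Rbfox1 lies at -1.89 and Ifi27l2a at 1.36.

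By size alone, 52 genes were at least 2-fold higher and 281 at least 2-fold lower in adipocyte-like nuclei of the library labelled KO, of 12320 counted; 13 of the 52 are mitochondrial. Many lower genes belong to other cells: markers of skeletal muscle had a median log2 ratio of -1.39 in these nuclei, endothelial markers -0.73, pericyte/smooth muscle markers -0.48, erythroid markers -0.44, macrophage/monocyte markers -0.42, fibroblast/progenitor markers -0.30 and Schwann markers -0.22. Without genes whose CPM lay below that of all other nuclei, 27 genes were higher and 83 lower. Thinning each nucleus to 1000 UMIs left 152 lower, and a minimum of 20 UMIs gave 108 higher and 499 lower. Cluster 2 held the largest share of adipocyte-like nuclei of Flox (34.4%, against 33.4% in cluster 1 and 28.2% in cluster 3). In KO it was cluster 1 (51.2%, against 30.2% in cluster 2 and 15.4% in cluster 3). The makeup of the class thus differed, and cluster 3, led by Gbp genes, held a smaller share in KO.

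Heat shock genes had a median of 0.00 in adipocyte-like nuclei, yet Hspa1b, an inducible HSP70, had 451 UMIs in Flox and 28 in KO (log2 ratio -4.04). Those UMIs lay in 30 nuclei of Flox, 326 of them in 1 nucleus, and in 28 nuclei of KO, so the share of nuclei with the transcript was 0.338% and 0.340%. Hspa1a, its neighbour and near copy, had 115 UMIs in 15 nuclei of Flox and 17 in 16 nuclei of KO. Among the relatives of NFE2L1, Bach2 (-1.47) and Mafg (-0.68) were lower, and the list of CNC and small MAF factors had a median of -0.24. Glutathione reductase, Gsr, stood at 40.0 CPM in Flox and 20.5 in KO, while the antioxidant list had a median of -0.06 and catalase, Cat, a log2 ratio of 0.48. ER stress genes had a median of 0.19 (percentile 99.97), with Calr at 0.43 and Atf5 at -0.60. Ferroptosis genes had a median of 0.12, with the lipid peroxide reductase gene Gpx4 at 0.43.

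In lipid synthesis the fatty acid and triglyceride list had a median of 0.06, with Elovl6 (0.52) and Dgat2 (0.43) higher, and the cholesterol list a median of -0.15, with Mvd at -0.67. Glucose uptake and glycolysis genes had a median of 0.13, with Pgam1 at 0.62 and Pdk4 at 0.54. Angiogenic factors had a median of -0.07, with Angptl4 at 0.63 and Angpt2 at -0.80. Medians were 0.08 for white adipose depot genes, -0.03 for creatine and calcium cycling, 0.13 for the cell cycle, 0.12 for immediate early genes, -0.12 for p53 and cell cycle arrest, 0.09 for inflammatory signalling and -0.02 for the interferon response, which was 0.65 without cluster 3. The lists for matrix and fibrosis (-0.30), tissue-resident macrophages (-0.58) and lipid-associated macrophages (0.16) mostly hold genes of other cells, and fibroblast/progenitor and macrophage/monocyte markers had medians of -0.30 and -0.42 in the same nuclei. None of the sex-linked genes fixed for a check of the libraries reached 50 UMIs in adipocyte-like nuclei.

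Ucp1, the uncoupling protein of brown fat, was sparse in both libraries. Adipocyte-like nuclei held 1000 Ucp1 UMIs (35.6 CPM, 33.4 to 37.9) in Flox and 924 (31.6 CPM, 29.6 to 33.7) in KO, a log2 ratio of -0.17 (-0.30 to -0.04). That ratio was -0.35 with classes from marker scores and -0.57 without cluster 3, an alternative chosen after seeing the data. Clusters 1 and 2 had 61.1 and 39.7 CPM in Flox against 35.8 and 28.4 in KO, but cluster 3 had 11.0 in Flox and 35.3 in KO. With each nucleus thinned to 1000 UMIs, 3.12% (2.77 to 3.51) of adipocyte-like nuclei in Flox and 2.99% (2.62 to 3.39) in KO had a Ucp1 UMI, after leaving out 100 and 507 shallower nuclei. Endothelial-like nuclei, which should lack the gene, gave 2.94% (1.94 to 4.25) in Flox and 7 of 698 nuclei (0.404% to 2.06%) in KO. Against these nuclei the share in Flox was not told apart from background RNA, while that in KO lay above it. Ucp1 stood at 33.3 CPM in Flox and 16.2 in KO in endothelial-like nuclei, and with this unequal background the direction of the log2 ratio of -0.17 is not settled. In Flox, Ucp1 stood lower in fibroblast/progenitor-like (15.2 CPM, 11.5 to 19.7) and macrophage/monocyte-like nuclei (15.3 CPM, 8.75 to 24.8). Against those 2 classes adipocyte-like nuclei of Flox lay above background. T/NK-like nuclei of Flox, with 9 UMIs, had 37.7 CPM, and nuclei in no named class had 70.7. Unthinned shares were 8.36% and 8.74% in adipocyte-like nuclei, at median depths of 2754 and 3090 UMIs, and 4.46% and 2.60% in endothelial-like nuclei, at 1257 and 1611 UMIs.

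Endothelial-like nuclei showed the opposite of adipocyte-like nuclei in energy metabolism, though other classes shared part of the drop in respiratory chain genes. In endothelial-like nuclei these genes had a median log2 ratio of -0.77 (-0.86 to -0.70, percentile 0.00). There 21 of 30 were at least 1.5-fold lower in the library labelled KO. The same list had medians of -0.31 in pericyte/smooth muscle-like, -0.26 in macrophage/monocyte-like and -0.13 in fibroblast/progenitor-like nuclei, but 0.09 in T/NK-like nuclei. In endothelial-like nuclei, Cox7a1 stood at 98.2 CPM in Flox and 40.9 in KO, and Uqcrfs1, a subunit of complex III, at 111 and 47.2. Per UMI of the class, Cox7a1 and Cox8b were more abundant in endothelial-like than in adipocyte-like nuclei of Flox. Cox7a1 had 245 of 2493687 UMIs against 805 of 28094486, and Cox8b had 701 against 3101. Whether endothelial-like nuclei made these transcripts is not settled by the counts. Fatty acid oxidation genes had a median of -0.71 (percentile 0.00), led by Acadvl (-1.26) and Etfb (-1.17), with 11 of 17 at least 1.5-fold lower. With doublets kept, the 2 medians were -0.48 and -0.34. With doublets removed by an automatic threshold, chosen after seeing the data, they were -0.58 and -0.31, but this setting removed 1082 barcodes in Flox and 1 in KO. The medians were -0.46 for glycolysis and for thermogenic genes and -0.30 for the proteasome. Immediate early genes had a median of 0.49 (percentile 100), but of 8 measured 2 were at least 1.5-fold higher and 1 at least 1.5-fold lower, with Egr1 at 1.45 and Junb at -0.63. Hes1, a target of Notch signalling, stood at 34.1 CPM in Flox and 96.4 in KO and Stxbp6 at 284 and 677, while Apold1 and Lhfpl3 had log2 ratios of 1.21 and 1.40, but 16 of 73 Lhfpl3 UMIs in KO lay in 1 nucleus. Lower genes were the muscarinic receptor gene Chrm3 (-2.32, 33 of 173 UMIs of Flox in 1 nucleus), Apba1 (-1.68), Hsd17b10 (-1.55) and Spg7 (-1.42), and the muscle genes Myh4 (-2.19) and Acta1 (-1.85). Markers of other cells were lower in these nuclei, with medians of -1.57 for skeletal muscle, -0.53 for fibroblast/progenitor, -0.43 for macrophage/monocyte and -0.21 for adipocyte markers. In all, 29 genes were at least 2-fold higher and 148 lower, of 8690 counted. Keeping only genes not below their CPM in other nuclei, an alternative chosen after seeing the data, left 27 and 55.

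Fibroblast/progenitor-like nuclei had slightly higher matrix genes in the library labelled KO, with a median log2 ratio of 0.16 (0.08 to 0.18, percentile 100) and 20 of 26 genes above 0, though 0 were at least 1.5-fold apart. The collagen gene Col6a1 had a log2 ratio of 0.37 and the crosslinking enzyme Lox 0.38, while Postn stood at -0.52. With the automatic threshold and its unequal removal, the median of the matrix list was -0.04. ER stress genes had a median of 0.23 (percentile 99.93), with Dnajb9 at 0.76. In the same nuclei the class's own markers had a median of 0.10 (percentile 99.9), while adipocyte markers had -0.13, endothelial markers -0.27 and skeletal muscle markers -1.27. The makeup of the class differed, with cluster 4 holding 69.5% of its nuclei in Flox and 61.5% in KO, and cluster 6 29.2% and 37.1%. Zfp949 (2.17), Rtl4 (1.89), Thbs4 (1.86), the mesenchymal transcription factor Twist1 (1.47) and transferrin, Trf (1.45), were among the genes furthest above 0. Nxph1 (-3.11), Clstn2 (-1.85), the secreted Wnt modulator Sfrp4 (-1.41), Sgcz (-1.27), Shisa9 (-1.15) and Fam227b (-1.10) were furthest below. Single nuclei weighed on 4 of these: 46 of 154 Sfrp4 UMIs and 38 of 84 Sgcz UMIs in Flox, and 27 of 82 Rtl4 UMIs and 13 of 75 Thbs4 UMIs in KO, lay in 1 nucleus each. Counts at 2-fold were 51 higher, 13 of them mitochondrial, and 60 lower, of 10010 genes; over the alternatives they ran from 46 to 88 and from 28 to 89.

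Macrophage/monocyte-like nuclei of the library labelled KO had more transcript of antioxidant genes and of lipid-associated macrophage genes. The antioxidant list had a median log2 ratio of 0.36 (0.16 to 0.51, percentile 100), with 4 of 17 genes at least 1.5-fold higher, and 0.16 with each library clustered alone. Hmox1, heme oxygenase, stood at 46.9 CPM in Flox and 108 in KO. Gclc, which makes the glutathione precursor, stood at 44.0 and 133, but 82 of its 138 UMIs in KO lay in 1 nucleus. Without it the log2 ratio was 0.40, and 6.90% of the nuclei in Flox and 10.0% in KO had the transcript. Lipid-associated macrophage genes had a median of 0.23 (percentile 99.94), led by the elastase gene Mmp12, with 12 UMIs in 6 nuclei of Flox and 128 in 13 nuclei of KO, and Gpnmb (0.60, with 125 of 500 UMIs of Flox in 1 nucleus). The tissue-resident macrophage list had a median of 0.02, which ran from -0.16 to 0.19 over the alternatives. Markers of other cells were lower in these nuclei, with medians of -1.29 for 2 measured skeletal muscle markers, -0.82 for 3 erythroid markers and -0.33 for 31 adipocyte markers. Dusp1 (1.67), Ddit4 (1.52), Klf2 (1.35) and Ifi27l2a (1.21) were higher, and Neurl3 (-1.02), Cd40 (-0.88), Irf1 (-0.85), Hpgd (-0.85), Map2k6 (-0.82) and Abi2 (-0.80) lower. Of 6573 genes, 42 were at least 2-fold higher, 9 of them mitochondrial, and 56 lower; over the alternatives these counts ran from 27 to 117 and from 14 to 123.

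Pericyte/smooth muscle-like nuclei differed first in their makeup: the smooth muscle cluster, led by Myocd, Acta2 and Tagln, held 57 of 350 nuclei in Flox and 17 of 221 in KO. These genes (-1.55, -1.04 and -1.25) and Galnt16 (-1.13), Synpo2 (-1.10) and Kcnab1 (-1.06) were the furthest below 0. In Flox, 31 of 85 Tagln UMIs and 24 of 114 Kcnab1 UMIs lay in 1 nucleus each; without its top nucleus Tagln had -1.04. Furthest above were Nfkbia, an inhibitor of NF-kB (1.52), Zfp949 (1.39), Lrrc8b (1.28), Rhob (1.21), Ntng1 (1.17) and Ehd1 (1.05). Fatty acid oxidation genes had a median of -0.45, and adipocyte markers had -0.41 in the same nuclei; with doublets removed by the automatic threshold, the oxidation median was 0.16, under the same unequal removal. Endothelial markers had a median of 0.47 in this class (percentile 99.99), with 5 of 14 at least 1.5-fold higher. Of 4690 genes, 36 were at least 2-fold higher and 71 lower, with 30 to 85 and 33 to 103 over the alternatives. T/NK-like nuclei, 103 in Flox and 119 in KO, had higher Actb (1.56), Tmsb4x (1.54), the ribosomal protein gene Fau (1.62), Tpt1 (1.47), Eef2 (1.26) and Klhl6 (1.55) and lower Pde4d (-1.31), Kat6b (-1.25), Snx29 (-0.99) and Gbe1 (-0.99). Single nuclei weighed here too: 77 of 201 Pde4d UMIs, 27 of 143 Tmsb4x UMIs and 22 of 110 Tpt1 UMIs in KO lay in 1 nucleus each. The mast cell proteases Cpa3 (103 and 42 UMIs) and Mcpt4 (71 and 33 UMIs) were lower as well, but their transcripts lay in 8 nuclei each of Flox and in 3 and 4 nuclei of KO. Of 5 mast cell markers measured, 4 were at least 1.5-fold lower. Immunoproteasome genes had a median of 0.50 in T/NK-like nuclei, but 0.19 with doublets kept, 0.11 with the automatic threshold and 0.81 with each library clustered alone. Both measured erythroid markers were higher in this class, with a median of 1.43, whereas the erythroid medians lay below 0 in the other 5 compared classes. There 104 genes were at least 2-fold higher, 10 of them mitochondrial, and 75 lower, of 2480, and the lower count ran from 22 to 247 over the alternatives.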

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

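Both tests of explanations in this part were set before their results were seen. Among 357 genes named by the fixed rule in any class, 12 were at least 1.5-fold higher in the library labelled KO in 1 class and at least 1.5-fold lower in another; with 1 library per genotype these differences were not tested, and 11 of them are given. Differences of log2 ratios are given in the order of the classes.

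Between adipocyte-like and endothelial-like nuclei, the log2 ratio of Acot2 differed by 2.34 (1.03 and -1.32), that of Cox7a1 by 2.05 (0.80 and -1.26) and that of Cox8b by 1.60 (0.83 and -0.77). Cox4i1 differed by 1.70 between T/NK-like and endothelial-like nuclei (0.67 and -1.03). Macrophage/monocyte-like and adipocyte-like nuclei differed by 1.76 for Cpt1a (1.03 and -0.72), by 2.38 for the phosphatase gene Dusp1 (1.67 and -0.71) and by 1.65 for Gsr (0.68 and -0.97). Pericyte/smooth muscle-like and fibroblast/progenitor-like nuclei differed by 2.66 for Clstn2 (0.81 and -1.85) and by 1.30 for the natriuretic peptide receptor gene Npr3 (0.65 and -0.66). Synpo2 differed by 1.79 between adipocyte-like and pericyte/smooth muscle-like nuclei (0.68 and -1.10), and Thrsp by 1.77 between T/NK-like and macrophage/monocyte-like nuclei (1.09 and -0.69). Many counts were small, given here as UMIs in Flox and KO. Adipocyte-like nuclei had 74 and 124 for Synpo2 and 129 and 82 for Dusp1. Macrophage/monocyte-like nuclei had 26 and 83 for Dusp1, 54 and 86 for Gsr, 54 and 110 for Cpt1a and 153 and 94 for Thrsp. T/NK-like nuclei had 50 and 100 for Thrsp and 56 and 84 for Cox4i1. Fibroblast/progenitor-like nuclei had 94 and 20 for Clstn2 and 71 and 35 for Npr3. Synpo2 had 86 and 27 in pericyte/smooth muscle-like nuclei. Endothelial-like nuclei had 128 and 39 for Acot2 and 245 and 78 for Cox7a1. The filter against free RNA was not applied to these pairs.

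In endothelial-like nuclei of the library labelled KO, the respiratory chain list was lower while in adipocyte-like nuclei it was higher. The list was also below 0, by less, in pericyte/smooth muscle-like (-0.31), macrophage/monocyte-like (-0.26) and fibroblast/progenitor-like nuclei (-0.13). Of these, only fibroblast/progenitor-like nuclei were used in the comparison that follows. Free RNA from adipocytes as the whole cause was predicted to lower the list alike in both classes, per CPM of drop in Ucp1. The list dropped by 143 CPM in endothelial-like and by 19.3 in fibroblast/progenitor-like nuclei, a ratio of 7.41 (3.47 to 17.5). That prediction need not hold if free RNA of the 2 libraries carried the list and Ucp1 in different proportions. In adipocyte-like nuclei the list was at 0.22 and Ucp1 at -0.17, so this comparison does not decide on free RNA. Adipocytes caught in the same droplet would bring their abundant genes. The 20 most abundant genes at least 4-fold higher in adipocyte-like than in endothelial-like nuclei had a median log2 ratio of only -0.31 (-0.36 to -0.26) in endothelial-like nuclei. This argues against droplets that bring RNA in the proportions of adipocyte-like nuclei as the whole cause. Cox7a1 and Cox8b were not among the 20 genes, and adipocyte RNA in other proportions was not tested. Adipocyte markers were below 0 too, with a median of -0.21, and free RNA from adipocytes stays open as a source of part or all of the drop. With doublets kept the list median was -0.48 against -0.77, so its size depended on how doublets were handled; the cause of that was not tested. Skeletal muscle markers fell further in these nuclei, with a median of -1.57, and RNA from muscle was not tested as a source. Effects of the genotype on endothelial cells and differences between the animals or preparations stay open, as 1 library per genotype cannot separate them.

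Among the nuclei in no named class were those of clusters 12 and 13. Cluster 12 held 174 nuclei, 106 in Flox and 68 in KO, and was led by the globin genes Hbb-bs and Hba-a1 and by the endothelial genes Vwf and Plvap. Cluster 13 held 172 nuclei, 110 in Flox and 62 in KO, and was led by Gpr141, Btla and the antigen presentation genes Cd74 and H2-Ab1.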

How the results depend on the processing

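The alternatives chosen after seeing the data were Scrublet's automatic doublet threshold for shares and for ratios (which removed 1082 barcodes in Flox and 1 in KO), leaving out the adipocyte-like cluster led by Gbp genes, and the filter against free RNA in classes other than adipocyte-like. No paired analysis was possible because there was 1 library per genotype. Of 1468 values of 146 results under all alternatives, 1306 stayed within the interval of the value first given (counts within 1.5-fold), 161 moved further and 1, a named gene, was reversed. Among the values that moved further, 13 list medians whose first value was below 1.5-fold lay on the other side of 0. The medians of gene lists in adipocyte-like nuclei kept their sign in 363 of 392 values. Where no cause is named, the cause was not tested.

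In adipocyte-like nuclei, TMM factors gave log2 ratios of 1.33 for Nfe2l1, 0.26 for thermogenic, 0.33 for lipolysis, 0.35 for fatty acid oxidation and 0.30 for respiratory chain genes. The mean CPM over nuclei gave 1.32 for Nfe2l1 and 0.21 for fatty acid oxidation. Thinning gave 0.24 for fatty acid oxidation, 0.17 for the respiratory chain and 152 genes at least 2-fold lower. Without the Gbp-led cluster, values were 1.35 for Nfe2l1, -0.57 for Ucp1, 0.068 for thermogenic, 0.20 for fatty acid oxidation and 0.16 for respiratory chain genes, and Gbp11, which leads that cluster, changed sign to 0.73. Classes from marker scores gave a share ratio of 1.30 and a Ucp1 log2 ratio of -0.35. A minimum of 20 UMIs, which lets in more genes, counted 108 higher and 499 lower, and the filter against free RNA, which removes genes, 27 and 83. The share with a Ucp1 UMI was 1.76% in Flox and 1.51% in KO at 500 UMIs and 8.36% and 8.74% unthinned, which follows from depth.

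In endothelial-like nuclei, the respiratory chain median was -0.68 at 500 genes or more, -0.53 at 5% mitochondrial UMIs or less, -0.48 with doublets kept, -0.58 with the automatic threshold, and -0.66 both at resolution 1.0 and with each library clustered alone. The fatty acid oxidation median was -0.52 at 5% mitochondrial UMIs or less, -0.34 with doublets kept and -0.31 with the automatic threshold. Genes lower numbered 87 with the automatic threshold, 97 with each library clustered alone and 55 with the filter against free RNA. In fibroblast/progenitor-like nuclei, the matrix median was 0.21 with doublets kept and -0.041 with the automatic threshold, which counted 88 genes higher, and the filter against free RNA counted 28 lower.

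In macrophage/monocyte-like nuclei, the tissue-resident median was 0.13 with doublets kept, -0.16 with the automatic threshold, -0.047 at resolution 0.3, 0.19 with each library clustered alone and 0.18 with marker scores. The antioxidant median was 0.16 with each library clustered alone. Genes lower numbered 96 with doublets kept, 37 with the automatic threshold and at resolution 1.0, 30 at resolution 0.3, 123 with each library clustered alone, 102 with marker scores and 14 with the filter against free RNA. Genes higher numbered 117 with the automatic threshold and 27 with that filter. In pericyte/smooth muscle-like nuclei, the fatty acid oxidation median was -0.12 with doublets kept and 0.16 with the automatic threshold, marker scores counted 85 genes higher and the filter 33 lower. In T/NK-like nuclei, the immunoproteasome median was 0.19 with doublets kept, 0.11 with the automatic threshold and 0.81 with each library clustered alone, and genes lower numbered 34, 28 and 247 under these and 22 with the filter.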

Other observations

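The tests of explanations for Nfe2l1 and for Kng1 in this part were chosen after the results were seen. Zfp949, a zinc finger gene, was higher in the library labelled KO in the 5 compared classes with at least 50 UMIs of it, with log2 ratios from 0.92 to 2.17; in adipocyte-like nuclei it stood at 44.1 CPM in Flox and 112 in KO. Of 15 genes of the circadian clock list, 2 were at least 1.5-fold lower and 0 higher in adipocyte-like nuclei. Arntl, which encodes the activator BMAL1, had a log2 ratio of -1.48 in adipocyte-like and -1.43 in endothelial-like nuclei, and Npas2 had -1.16 in adipocyte-like nuclei. Per1, a repressor, had 0.36 in adipocyte-like and 0.62 in fibroblast/progenitor-like nuclei. The circadian clock list had a median of 0.11 in adipocyte-like nuclei (percentile 99.14), with 8 of 15 genes above 0, and -0.027 without the adipocyte-like cluster led by Gbp genes. The hours at which tissue was taken are not given in the sources used here.

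Nfe2l1 transcript was higher, not lower, in adipocyte-like nuclei of the library labelled KO. Exchanged labels would put the proteasome genes, which NFE2L1 is known to drive, above 0 in that library. Their median log2 ratio was -0.46 (-0.48 to -0.37), which argues against it. The argument is limited, because the list was also at -0.30 (-0.43 to -0.23) in endothelial-like nuclei, where the Nfe2l1 ratio was 1.14 (0.949 to 1.36). The drop was thus not confined to nuclei in which Nfe2l1 differed. A different mix of adipocyte-like clusters is also argued against, since the lowest log2 ratio of Nfe2l1 within a cluster was 0.99 (0.89 to 1.10). A candidate explanation that stays open is a deletion of part of the gene that leaves its 3' end transcribed; it was not tested, because the deleted part is not given and the counts hold no positions within the gene.

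Kng1 was nearly absent from the library labelled Flox and present in 1492 adipocyte-like nuclei of the library labelled KO. Reads of its paralog Kng2 counted as Kng1 would keep their ratio, but there were 0.00158 Kng1 UMIs per Kng2 UMI in Flox and 0.467 in KO, a ratio of 295.6 (115.3 to 1085.9). Extra copies of the segment that holds Adipoq and Kng1, as a transgene built from that segment would bring, may be a cause and stay open: the 4 other measured genes within 100 kb of Kng1 had a median log2 ratio of 0.70, above 99.9% of 12239 runs of neighbouring genes. These values had prompted the explanation and so do not test it, and St6gal1, beyond that distance, had -0.08. Whether the KO mice carry such a transgene is not given in the sources used here. A strain difference on chromosome 16 also stays open and was not tested.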
